A study of Mus musculus with 16 samples.

How the data were processed

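Total RNA of 2 cell types, WT and M833, was measured on two-colour arrays against a common reference RNA. Per the labels' protocols the RNA was extracted with Trizol and labelled by reverse transcription with dye-coupled nucleotides, and the design was one of colour-swapped replicates. Each cell type had 8 arrays, 4 with the sample in Cy5 and 4 with the sample in Cy3. Arrays were grouped by their titles, and replicates were numbered in the order of the series because the labels give no numbers.

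The deposited values are log ratios, taken as log2, which the authors had already normalised, and per the submitters' processing notes limma was used for them, with no version given. The background correction, the normalisation method and any filters are not given in the sources used here. The log2 scale was taken from the values, since the largest, 15.35, fits the range of a 16-bit scanner as a log2 ratio and not as a natural log. Medians of the arrays lay between -0.02 and 0.07, so that the values were close to centred, and the centring itself is not described. The direction, sample over reference, is likely but not stated. It rests on the titles, which name the cell type before the reference, on a positive correlation of every pair of arrays, which shows that one dye orientation had already been turned, and on low ratios of globin and albumin in fibroblast cultures. No sign was turned here. Channel intensities were not used here, so that dim probes could not be filtered.

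Probes were named through the platform annotation, which is old. Of 15247 probes 9600 had one gene symbol, 214 several and 5433 none, and 9492 of the first were matched through their Entrez gene number to a current gene table, which changed 0 symbols. Probes of one gene were averaged, for 1810 genes with several probes, and probes without one symbol were kept as single features without a name. This left 12761 features, of which 7114 were named genes. The filter on missing values, 6 of 8 arrays per cell type, removed nothing because there were 0 missing values. Of named genes shown in the text, 32 had several probes, and in 1 of them, Tfrc, the probes differed in sign.

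Features were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) on all 16 arrays, with cell type and dye orientation as terms, so that gene-specific dye bias is taken up and the reference cancels in M833 minus WT. Benjamini-Hochberg adjusted p-values under 0.05 over all features were called, and a second count asked for a log2 difference of at least 1. The dye orientation by cell type interaction was tested in a model with that term. The mean of each cell type was tested against 0 for the comparison with the reference. Errors are standard errors of the fitted difference, or SDs over the arrays of a cell type after adjustment for dye. The standard errors and confidence intervals treat the arrays as independent and do not allow for sets of arrays that deviated together. The arrays of a feature were counted as lying apart where all 4 arrays of one cell type exceeded all 4 of the other in both dye orientations, in the same direction.

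Before the data were examined 35 gene lists were fixed, of pathways and of cell type markers, and 33 of them had at least 3 measured genes. Their shift was tested with camera at a preset correlation between genes of 0.01, and beside it with an estimated correlation, with fry, and with an exact two-sided permutation of the mean of the list within dye orientations, whose smallest possible p is 0.000408. P-values were adjusted over the 33 lists. The genes to be named were fixed by rule at the same time: Met, the 12 largest increases and 12 largest decreases among called genes with the same sign in both dye orientations, up to 4 called members per list in its main direction and up to 2 against it, measured sex-linked genes, and the 6 highest and 6 lowest genes of each cell type against the reference. Genes named outside this rule, such as Mki67, Ccna2, Hspa5, C1qc and Agt, were chosen after their values were seen.

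The fit was tested on simulated data with the spread of these arrays over 12761 features. It recovered 62% of features changed by 0.25 on the log2 scale, 94% at 0.5, 98% at 1 and 98% at 2, with 5 false calls. The simulated noise was independent between arrays, so these rates do not hold for sets of arrays that deviate together. Alternatives fixed before the data were examined were centring each array on its median, scaling between arrays, no dye term, each probe by itself, array weights, robust moderation, no moderation, one dye orientation at a time, leaving out each array, leaving out 3 M833 arrays of a second slide number series, and the estimated correlation and fry for lists. Alternatives added after seeing the data set extreme values missing, took sets of 4 arrays that deviated together as a random block or as 1 replicate, and left out either set of WT arrays.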

Results

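The data were 16 two-colour expression arrays of mouse cells, with 8 arrays of the cell type WT and 8 of the cell type M833. The series title speaks of Met mutations in MEFs, the usual abbreviation for mouse embryonic fibroblasts, and the labels do not say what M833 stands for. Each array carried a cell sample in one dye and a common reference RNA in the other, and in each cell type 4 arrays had the sample in Cy5 and 4 in Cy3. Ratios were read as sample over reference on the log2 scale, a direction that the titles and values make likely but that no label states. The comparison of M833 with WT asked which transcripts differed between the cell types, and the ratio to the reference placed each cell type against an RNA whose make-up the labels do not give. A value was available for 15247 probes on every array, which gave 12761 features after probes of one gene were averaged, 7114 of them named genes. Pairs of arrays correlated with r from 0.591 to 0.973 over all probes, and with r of at least 0.818 without WT replicate 2, an array with 49 values above 8 on the log2 scale. Nothing in the labels says that the arrays came from separate cultures, so p-values measured only the spread between these arrays, which may be technical. The number of arrays limited the precision. Met itself, named in the series title, had 0 probes under that symbol, so no value could be given for it, and whether one of the 5433 probes without a symbol belongs to it is unknown.

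The largest increase in M833 was in Mdk, which encodes the secreted growth factor midkine. Mdk was 3.10-fold higher in M833 than in WT, a log2 difference of 1.63 ± 0.19 (SE, n = 8 per cell type). It lay below the reference in both cell types, at -3.41 in WT and -1.77 in M833. The difference of Mdk was 1.16 without WT replicates 1, 2, 5 and 6 and 2.10 without WT replicates 3, 4, 7 and 8. The fast muscle myosin light chain gene Mylpf was 1.04 ± 0.23 higher and the cartilage collagen gene Col2a1 0.97 ± 0.16 higher on the same scale. The largest decreases were in Lyz2, encoding lysozyme of macrophages, at -1.67 ± 0.14, and in the complement gene C1qb at -1.45 ± 0.04. Lyz2 was at -1.31 without WT replicates 1, 2, 5 and 6 and at -2.03 without WT replicates 3, 4, 7 and 8. The complement gene C1qa, at -1.17 ± 0.07, was also among the 12 largest decreases. Mgp, whose product inhibits mineralisation of matrix, was lower by a log2 difference of -1.21 ± 0.26, and the stress-induced gene Nupr1 by -1.20 ± 0.13. Other genes among the 12 largest increases were the mitotic genes Nek2 (0.84), Plk1 (0.83), Kif2c (0.76), Cep55 (0.75) and Pbk (0.70), the replication licensing gene Mcm6 (0.75), the connexin gene Gja4 (0.78), Camta1 (0.78) and Fxyd6 (0.86). Other genes among the 12 largest decreases were C77713 (-1.10), Pisd-ps3 (-1.08), Ccdc80 (-0.996), the prostaglandin receptor gene Ptger4 (-0.96), Cdk8 (-0.96), Gm3636 (-0.94) and Tmed9 (-0.94). All 12 increases were higher in 8 of 8 M833 arrays than the WT mean, and all 12 decreases were lower in 8 of 8. As these genes were picked for their size on the same arrays, this adds little. The arrays did not lie apart in both dye orientations for Mylpf, Col2a1, Fxyd6, Gja4, Pbk and C77713. Adjusted p-values in limma ran from 9.6e-06 for Nek2 to 0.031 for Fxyd6 among these increases, and from 1.4e-11 for C1qb to 0.0027 for Mgp among these decreases. With the log ratios scaled between arrays, Mylpf fell short of the threshold at 0.13 (adjusted p = 0.718, limma), as did Col2a1 at 0.33 (adjusted p = 0.368), Fxyd6 (adjusted p = 0.081) and Gja4 (adjusted p = 0.054). The increase of Fxyd6 was present against WT replicates 1, 2, 5 and 6 and was 0.11 without them (adjusted p = 0.143), and its call was also lost without any one of these arrays or without M833 replicate 1 or 7. With sets of 4 arrays that deviated together as a random block Fxyd6 (adjusted p = 0.0644, limma) and Gja4 (adjusted p = 0.123) were not called. Without the same 4 WT arrays Gja4 was at 0.44 (adjusted p = 0.141), while Mylpf at 0.53, Mgp at -0.56 and C77713 at -0.53 kept their calls. Without WT replicates 3, 4, 7 and 8 these genes differed more, with Mgp at -1.86, and Kif2c (0.47), Mcm6 (0.41) and Pbk (0.38) differed less and kept their calls.

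**Figure D1:**
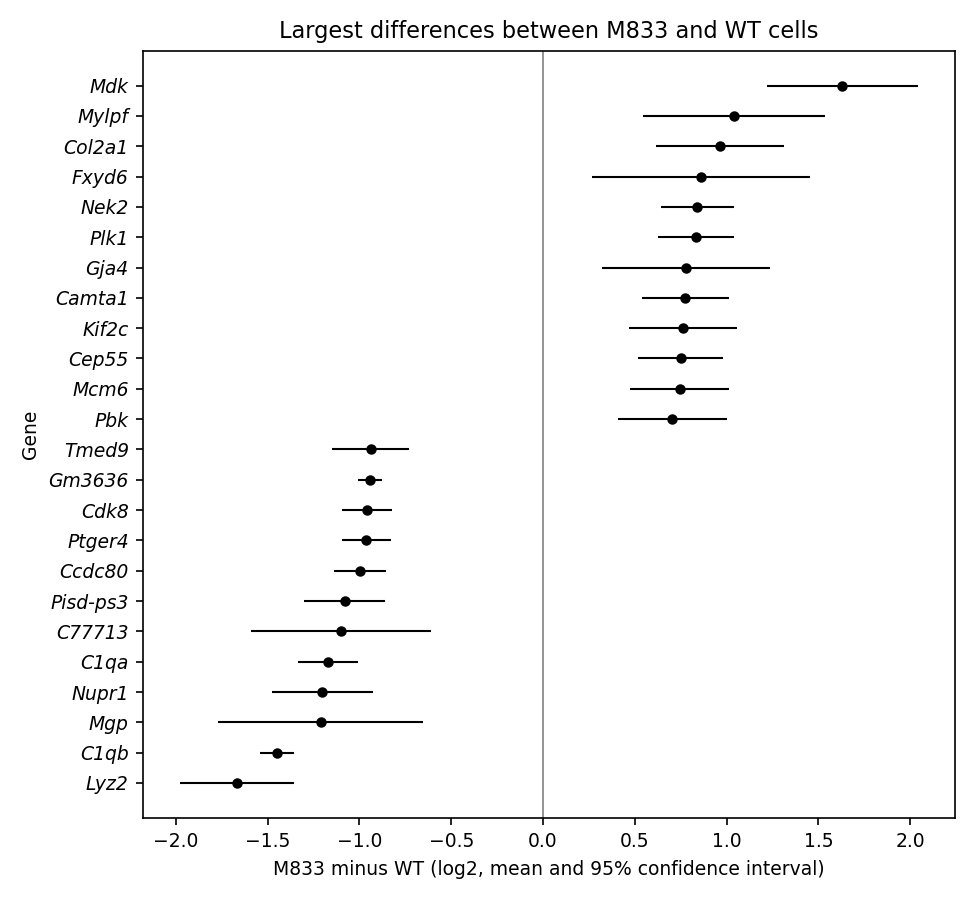
For the 12 genes with the largest increase and the 12 with the largest decrease in M833, points are the log2 difference M833 minus WT from 8 arrays per cell type and bars its 95% confidence interval, from Mdk at 1.63 down to Lyz2 at -1.67. The values of Mylpf, Col2a1, Fxyd6 and Gja4 did not pass the test once the log ratios were scaled between arrays. The bars treat the 8 arrays as independent, although the WT arrays deviated together in sets of 4, so they can be too narrow. For Mdk the bar ran from 1.22 to 2.04, while leaving out one or the other set of WT arrays gave 1.16 and 2.10.

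In all, 3301 of the 12761 features (25.9%) differed between M833 and WT in limma with dye orientation in the model, 1276 higher and 2025 lower in M833. Among named genes 929 were higher and 1338 lower. Most differences were small, with a median size of 0.22 on the log2 scale among the called features, and 10 features reached 2-fold, 2 of them higher (Mdk and Mylpf) and 8 lower. With each array centred on its median the split was 1558 higher and 1635 lower. In 1340 features all 4 M833 arrays lay beyond all 4 WT arrays in the same direction in both dye orientations, 512 higher and 828 lower, where chance gives 0.0408% of features or 5.21 if the 16 arrays are independent. If sets of 4 arrays are the units, 2 sets lie apart from 2 by chance in 33.3% of features. WT replicates 1, 2, 5 and 6 deviated together from replicates 3, 4, 7 and 8, and with such sets of 4 arrays in both cell types as a random block the count was 1465. With the mean of each set as 1 replicate, which leaves 2 against 2, limma called 0 features, with 1675 at an unadjusted p under 0.05 where 638 were expected.

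Genes of macrophages and other leukocytes were lower in M833. Of 19 genes in this marker list only 7 were measured, and all 7 fell, with a median log2 difference of -0.86 and 7 calls adjusted over the list alone. Besides Lyz2, C1qb and C1qa, the actin-bundling gene Lcp1 fell by 0.86 ± 0.06 and Fcer1g, which encodes the shared gamma chain of Fc receptors, by 0.81 ± 0.06 (SE, n = 8 per cell type). The smallest decrease of the list was in C1qc, at -0.55. The shift of the list passed camera with the preset correlation (adjusted p = 2.7e-10) and with an estimated correlation (adjusted p = 0.00058). It was the only list of the 9 called whose call held with the estimated correlation. At the preset correlation, calls of lists were also common when the arrays were regrouped at random. In 6 of the 7 genes every M833 array lay below every WT array in both dye orientations. The mean of the list ran from -0.40 to -0.34 over the WT arrays and from -1.54 to -1.29 over the M833 arrays.

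Cell cycle genes were higher in M833. Of 31 measured members 24 rose, none fell and 7 did not pass the test, with a median log2 difference of 0.52, and 25 rose when adjusted over the list alone. The replication licensing gene Mcm3 rose by 0.59 ± 0.04 and the ribonucleotide reductase gene Rrm2 by 0.49 ± 0.04. The mitotic kinase gene Aurka rose by 0.65 ± 0.06 and Cdca8, which encodes a chromosomal passenger protein, by 0.65 ± 0.06 (SE, n = 8 per cell type). Mki67, a common marker of cycling cells, had a log2 difference of -0.11 ± 0.14, which did not pass the test (adjusted p = 0.557, limma), and Ccna2 one of 0.16 (adjusted p = 0.534). The adjusted p of the list in camera was 8.4e-19 with the preset correlation, and its call was lost with an estimated correlation (adjusted p = 0.128). The WT arrays took 2 levels, with list means from -0.26 to -0.23 on replicates 1, 2, 5 and 6 and from -0.63 to -0.59 on replicates 3, 4, 7 and 8, against -0.06 to 0.12 over the M833 arrays. These also split, more narrowly, from -0.06 to -0.002 on M833 replicates 1, 2, 5 and 6 and from 0.08 to 0.12 on M833 replicates 3, 4, 7 and 8. The list median was 0.69 without the first of these sets of WT arrays and 0.29 without the other.

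**Figure D2:**
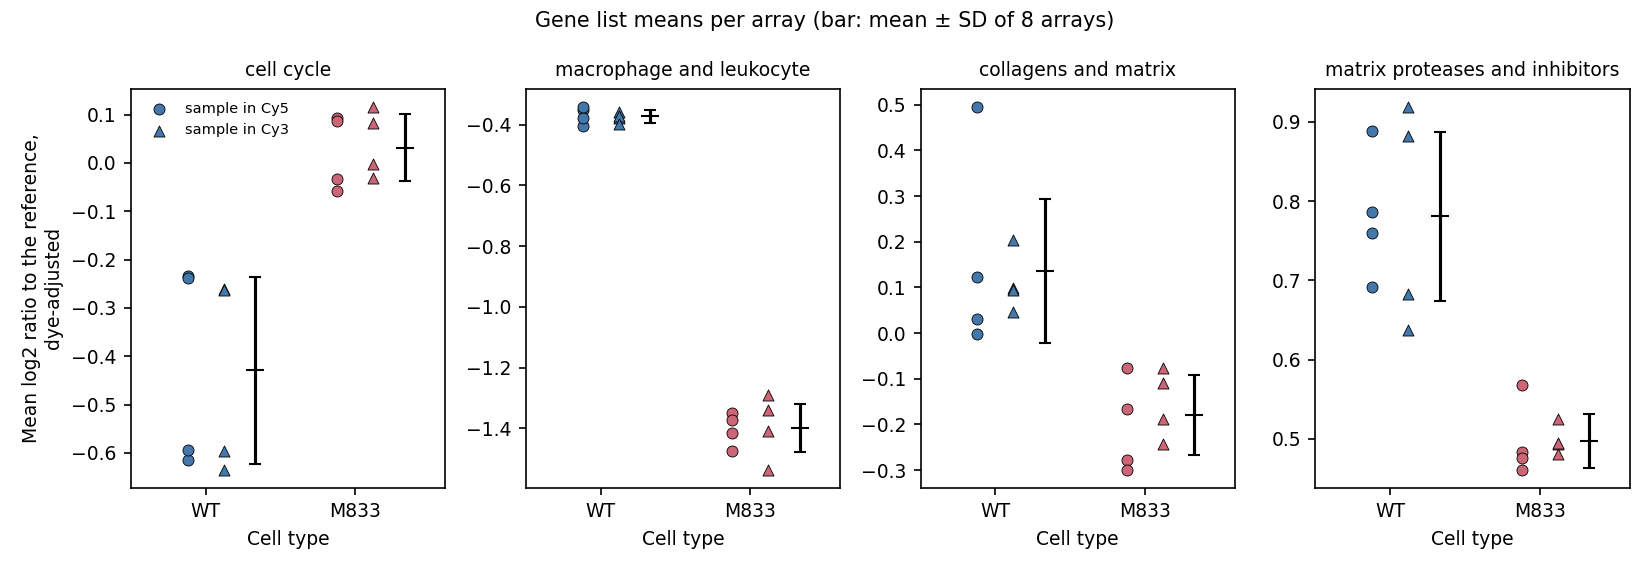
Mean log2 ratio to the common reference over the measured genes of 4 lists, after adjustment for dye, is plotted for each of 16 arrays, with circles for the sample in Cy5, triangles for the sample in Cy3 and bars for the mean ± SD of 8 arrays. The cell cycle means of WT lie at 2 levels, from -0.26 to -0.23 and from -0.63 to -0.59, the macrophage means of WT lie between -0.40 and -0.34, and the collagen and matrix mean of WT replicate 2, at 0.49, includes an extreme value of Vcan.

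The lists of matrix proteins and of matrix proteases with their inhibitors were lower in M833, with many members not past the test. In the list of collagens and matrix proteins 9 of 22 measured members fell and none rose, over all genes and adjusted over the list alone, with a median of -0.24. The fibrillar collagen genes Col1a2 (-0.87 ± 0.08) and Col5a2 (-0.56 ± 0.10) fell, as did Fbln2 (-0.48 ± 0.10) and the fibronectin gene Fn1 (-0.38 ± 0.06; SE, n = 8 per cell type). Among matrix proteases and their inhibitors 6 of 12 fell and 1 rose, again both over all genes and adjusted over the list alone, with a median of -0.32. The cathepsin gene Ctsb fell by 0.87 ± 0.04, the inhibitor gene Timp2 by 0.67 ± 0.06, Mmp23 by 0.50 ± 0.06 and Adamts4 by 0.41 ± 0.04, whereas Timp4 was higher by 0.35 ± 0.12. Ctsb and Ctsl (-0.47) were among the cathepsin genes set apart from the lysosomal list below. The 5 members that did not pass the test were Mmp2 (-0.15), Mmp9 (-0.17), Timp3 (-0.24), Adamts1 (-0.05) and Plaur (0.19). Of 6 measured fibroblast markers 4 fell, Col1a2, Col3a1 (-0.38), Col1a1 (-0.20) and Vim (-0.19), and the list median was -0.20, with 4 calls adjusted over the list alone. Of these 4 genes, Col1a2, Col3a1 and Col1a1 also stood in the collagen list. Adjusted p-values in camera were 0.0066 for the collagen list, 0.0044 for the protease list and 0.0152 for the fibroblast markers, and with an estimated correlation they were adjusted p = 0.244, 0.113 and 0.226. With log ratios scaled between arrays the protease list (adjusted p = 0.103) and the fibroblast markers (adjusted p = 0.134) missed the threshold, as did Fn1 (-0.06), Fbln2 (-0.11), Vim (-0.03) and Timp4 (0.25) by themselves. Without WT replicates 3, 4, 7 and 8 the adjusted p was 0.351 for the collagen list, 0.129 for the protease list and 0.0912 for the fibroblast markers, and without WT replicates 1, 2, 5 and 6 it was 0.0924 for the fibroblast markers, with Fbln2 at -0.30 and Col3a1 at -0.23 still called and Timp4 at 0.26 and Vim at -0.13 not. Members of the collagen and protease lists differed in both directions in these settings. Without WT replicates 3, 4, 7 and 8 there were 4 higher and 9 lower in the collagen list and 3 higher and 7 lower in the protease list, and without WT replicates 1, 2, 5 and 6 there were 1 and 13, and 1 and 9. With the sets as a random block 6 members of the collagen list, 6 of the protease list and 2 fibroblast markers were lower and none was higher, and Timp4 (adjusted p = 0.318, limma), Vim (adjusted p = 0.153) and Col1a1 (adjusted p = 0.0636) were not called.

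The amino acid and unfolded protein response list was lower in M833, with 9 of 22 measured members down, none up and a median of -0.16, and 14 down when adjusted over the list alone. The asparagine synthetase gene Asns fell by 0.38 ± 0.06, the amino acid transporter gene Slc3a2 by 0.36 ± 0.07, the stress-induced transcription factor gene Atf3 by 0.23 ± 0.05 and the chaperone gene Dnajb9 by 0.20 ± 0.04 (SE, n = 8 per cell type). The chaperone gene Hspa5 differed by -0.02 and did not pass the test (adjusted p = 0.868, limma). The adjusted p of this list in camera was 0.0054, and with an estimated correlation adjusted p = 0.226. It was adjusted p = 0.156 with log ratios scaled between arrays and 0.0629 without WT replicates 1, 2, 5 and 6, where 7 members were lower and 2 higher and Asns at -0.24 and Slc3a2 at -0.21 were still called. Without WT replicates 3, 4, 7 and 8 there were 14 lower and 1 higher, and Atf3 was at -0.13 and called. With the sets as a random block 5 were lower.

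Of 52 measured ribosomal protein genes 41 did not pass the test, 11 rose by small amounts and none fell, with the same counts adjusted over the list alone and a median of 0.04. The largest of these increases was in Rps27, at 0.28 ± 0.05, followed by Rps24 at 0.21 ± 0.04, while Rpl8 rose by 0.16 ± 0.04 and Rpl6 by 0.11 ± 0.02 (SE, n = 8 per cell type). The adjusted p in camera was 0.00013, with an estimated correlation adjusted p = 0.475, and the exact permutation test of the list mean within dye orientations gave a two-sided p of 0.0722. Adjusted over the lists this exact p was 0.119, the only one above 0.05 among the lists that camera called. The call of the list was also lost without WT replicates 3, 4, 7 and 8 (adjusted p = 0.287), where 5 members were higher and 4 lower and Rps27 was at 0.17, while 22 were higher and none lower without WT replicates 1, 2, 5 and 6. With the sets as a random block 1 member was higher, and Rps24, Rpl8 and Rpl6 were not called.

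Of 23 skeletal muscle markers only Mylpf, the troponin gene Tnnt1 and the embryonic light chain gene Myl4 were measured, and all 3 were higher in M833, over all genes and adjusted over the list alone. Tnnt1 was higher by 0.61 ± 0.16 and Myl4 by 0.17 ± 0.06 (SE, n = 8 per cell type). Both Mylpf and Tnnt1 were below the reference in both cell types, with Mylpf at -4.49 and Tnnt1 at -1.59 in M833. The adjusted p in camera was 0.0242, with an estimated correlation adjusted p = 0.128, and with log ratios scaled between arrays it was 0.201, with Tnnt1 at 0.27 and not called. The list missed the threshold without WT replicates 1, 2, 5 and 6 (adjusted p = 0.0627), as Tnnt1 did at 0.54, and without WT replicates 3, 4, 7 and 8 (adjusted p = 0.0912), as Myl4 did at 0.04. With the sets as a random block Mylpf alone was called (adjusted p = 0.029, limma). Among Hox and positional genes 4 of 7 measured members rose, the homeobox genes Meis2 (0.27 ± 0.05), Meis1 (0.20 ± 0.04) and Hoxb3 (0.29 ± 0.10) and the T-box gene Tbx3 (0.16 ± 0.05), with 4 also adjusted over the list alone. The list had a median of 0.16 and an adjusted p of 0.0318 in camera, and with an estimated correlation adjusted p = 0.244. Its call was lost without WT replicate 4 (adjusted p = 0.0508) or 6 (adjusted p = 0.0518), without WT replicates 1, 2, 5 and 6 (adjusted p = 0.104) and without WT replicates 3, 4, 7 and 8 (adjusted p = 0.146), where Tbx3 was at 0.08 and not called, and Hoxb3 missed the threshold in both of the last settings. With the sets as a random block 2 of the 7 members were higher, and Hoxb3 and Tbx3 were not called.

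The other 24 lists tested were not called by camera. In the list of HGF-MET signalling, the pathway of the receptor tyrosine kinase Met, 3 of 12 measured members fell, 1 rose and 8 did not pass the test, as they did adjusted over the list alone (median -0.07, adjusted p = 0.602). Plat, encoding tissue plasminogen activator, fell by 0.39 ± 0.04, the adaptor genes Cbl and Grb2 fell by 0.31 ± 0.08 and 0.21 ± 0.06, and Cd44 rose by 0.33 ± 0.10 (SE, n = 8 per cell type). Of 8 p53 targets 3 fell and none rose, over all genes and adjusted over the list alone (adjusted p = 0.168), namely Mdm2 (-0.52), Btg2 (-0.46) and Ccng1 (-0.32), of which Mdm2 and Ccng1 did not pass the test with log ratios scaled between arrays. Of 12 MAPK and immediate early targets 6 fell, among them Egr1 (-0.53), Ccnd1 (-0.33) and Fosl1 (-0.18), and Spred2 rose (0.16), with 6 and 1 also adjusted over the list alone and an adjusted p of 0.115. Of 12 genes of metal handling 5 fell, among them the metallothionein genes Mt2 (-0.57) and Mt1 (-0.51) and the ferritin gene Fth1 (-0.41), and Tfrc was higher at 0.40, although its probes ran from -0.21 to 0.75. Adjusted over the list alone 5 fell and 1 rose there too, and the adjusted p of the list was 0.413. The exact permutation test, which treats the arrays as independent, gave adjusted p = 0.0019 for metal handling. It gave 0.0415 for each of the p53, MAPK and interferon-stimulated lists. In fry the adjusted p of these lists was 0.0073, 0.0033, 0.0068 and 0.0141. HGF-MET signalling passed fry (adjusted p = 0.0306) but not the exact test (adjusted p = 0.398). The same held for one-carbon metabolism (fry adjusted p = 0.0035, exact 0.0548), senescence (0.0049 and 0.568), glycolysis and hypoxia (0.0070 and 0.143) and cytokines (0.0451 and 0.213). Fry and the exact test ask whether the genes of a list differ at all. Camera asks whether they differ more than the other genes, so the tests answer different questions. Several of the gene differences above rested on one set of WT arrays. Without WT replicates 1, 2, 5 and 6 Cd44 (0.08) and Spred2 (0.07) were not called, and Egr1 (-0.26) and Tfrc (0.18) were called. Without WT replicates 3, 4, 7 and 8 Cbl (-0.15), Grb2 (-0.08) and Mt1 (-0.33) were not called, and Mdm2 (-0.17), Btg2 (-0.29) and Ccnd1 (-0.19) were called. Spred2 was also not called with log ratios scaled between arrays, and with the sets as a random block Spred2, Cd44, Grb2 and Fosl1 were not called.

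The p-values of further lists describe markers of other cell types. Of 11 epithelial markers 2 passed the test, Elf3 (0.56) and Esrp1 (0.42), of which 1 did so adjusted over the list alone, and the adjusted p of the list was 0.0622. With log ratios scaled between arrays the difference of Esrp1 was -0.04 and that of Elf3 0.30, neither of them called, and without WT replicates 1, 2, 5 and 6 Elf3 (0.36) and Esrp1 (0.34) were not called either, nor was Esrp1 (0.49) without WT replicates 3, 4, 7 and 8. None of 4 endothelial, 5 erythroid, 13 germ and pluripotent cell or 3 keratinocyte markers passed the test, over all genes or adjusted over the list alone, with adjusted p-values in camera of 0.273, 0.273, 0.471 and 0.955. Of 7 neural and glial markers Nes passed (0.64 ± 0.22) and none did adjusted over the list alone (adjusted p = 0.273), and of 4 liver markers Apob passed in both counts (0.21 ± 0.05, adjusted p of the list 0.273) but not with log ratios scaled between arrays. The increase of Nes was present only against WT replicates 1, 2, 5 and 6, and without them its difference was 0.03 (adjusted p = 0.702, limma). With the sets as a random block Elf3, Esrp1, Nes and Apob were not called. Of the 3 cartilage and bone markers Col2a1 was higher and Mgp lower, as adjusted over the list alone, and Alpl, at 0.09, did not pass the test (adjusted p of the list 0.567). Adipocyte markers and sex-linked genes had 2 measured members each, too few for a test of the list. The adipocyte gene Lpl fell by 0.51 ± 0.15 and Agt had a difference of 0.05. The Y-linked gene Eif2s3y was lower by 0.35 ± 0.09 (adjusted p = 0.0069, limma) and the X-linked Xist had a difference of -0.08 ± 0.04 (adjusted p = 0.105). Without WT replicates 3, 4, 7 and 8 Eif2s3y was at -0.17 (adjusted p = 0.0792) and Xist at -0.12 (adjusted p = 0.0407).

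Metabolic and signalling lists held single changes in both directions. In methionine and one-carbon metabolism 5 of 18 rose and 3 fell, with Mthfd1 at 0.37 ± 0.03, the spermine synthase gene Sms at 0.41 ± 0.04 and Msrb3 at -0.32 ± 0.04 (list adjusted p = 0.273; SE, n = 8 per cell type, limma). NRF2 targets had 4 of 16 down and 2 up, the largest being the epoxide hydrolase gene Ephx1 at -0.93 ± 0.14 (list adjusted p = 0.747). In glycolysis and hypoxia 5 of 20 fell, among them Pdk1 (-0.36) and Adm (-0.48), and none rose (list adjusted p = 0.765). Of 23 growth factors and receptors 4 rose, Mdk, Erbb3 (0.32), Igfbp5 (0.19) and Igf1r (0.17), and 2 fell, Pdgfa (-0.30) and Gas6 (-0.22) (list adjusted p = 0.747). In the contractile and TGF-beta list 2 of 18 rose, Id3 (0.43) and Id2 (0.42), and 3 fell (list adjusted p = 0.752). The senescence list had 3 of 7 up, with the lamin gene Lmnb1 at 0.56 ± 0.07 and the cell cycle inhibitor gene Cdkn1b at 0.33 ± 0.07, and 1 down, Glb1 at -0.37 ± 0.07 (list adjusted p = 0.273). Of 16 imprinted genes 2 rose, Grb10 (0.23) and Dlk1 (0.22, but -0.22 with log ratios scaled between arrays), and Igf2r fell (-0.31; list adjusted p = 0.273). In oxidative phosphorylation 4 of 30 fell and 2 rose (list adjusted p = 0.196), and in cholesterol and fatty acid synthesis 1 of 15 rose, Fasn (0.19), and 1 fell, Nsdhl (-0.09; list adjusted p = 0.768). Of 9 Wnt and BMP regulators Fzd7 rose (0.16) and Dkk3 fell (-0.66; list adjusted p = 0.765). Among 9 interferon-stimulated genes Bst2 fell (-0.34; list adjusted p = 0.372), and among 6 cytokine and chemokine genes Csf1 fell (-0.45; list adjusted p = 0.898). Adjusted over the list alone, the counts up and down were 5 and 3 for one-carbon metabolism, 3 and 5 for NRF2 targets, 2 and 6 for glycolysis, 4 and 2 for growth factors, 2 and 5 for the contractile list and 3 and 1 for senescence. They were 2 and 1 for imprinted genes, 0 and 1 for oxidative phosphorylation, 1 and 0 for cholesterol synthesis, 1 and 2 for Wnt regulators, 0 and 1 for interferon-stimulated genes and 0 and 1 for cytokines. Calls that were lost without WT replicates 3, 4, 7 and 8 were those of Igfbp5 (0.04), Pdgfa (-0.04), Gas6 (-0.15), Grb10 (0.14), Dlk1 (0.11), Csf1 (-0.13) and Nsdhl (-0.07), while Glb1 (-0.19), Igf2r (-0.20) and Id2 (0.27) kept theirs. Without WT replicates 1, 2, 5 and 6 Erbb3 (0.18), Igf1r (0.13) and Nsdhl (-0.11) lost theirs, and Ephx1 (-0.61) and Adm (-0.27) kept theirs. With log ratios scaled between arrays Msrb3, Igfbp5, Erbb3, Grb10, Dlk1, Id2, Csf1 and Nsdhl were not called, and with the sets as a random block Igfbp5, Erbb3, Igf1r, Pdgfa, Gas6, Dlk1, Csf1, Bst2 and Nsdhl were not.

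The dye swap allowed the M833 minus WT difference to be measured in each dye orientation. Mdk was higher by 1.64 with the samples in Cy5 and by 1.62 with the samples in Cy3, and Lyz2 was lower by -1.63 and -1.70. Of 120 called genes chosen to be named, 7 were over 2 times as large in one orientation as in the other, among them Gja4 (0.37 in Cy5 and 1.19 in Cy3), Apob (0.07 and 0.35), Uqcrc1 (-0.29 and -0.02) and Igf2r (-0.17 and -0.44). Over all features 77.7% had the same sign in both orientations. Across features, which are not independent replicates, the differences of both orientations correlated with r = 0.574 and rho = 0.692. No feature had a dye orientation by cell type interaction in limma at an adjusted p under 0.05, and 361 had an unadjusted p under 0.05 where 638 were expected. Without the 3 M833 arrays of a second slide number series, which all carried the sample in Cy3, 7 features passed. The sets of WT arrays that deviated together were balanced over dye orientation. Their difference thus stayed in the residual spread of the interaction test and made it less able to find one. The absence of calls therefore does not show that the differences were free of a dependence on dye.

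Against the common reference, both cell types were high in S100a6, which encodes a calcium-binding protein, at 3.95 ± 0.19 in WT and 3.70 ± 0.15 in M833 (log2 ratio, SD, n = 8). In WT the next highest were Ephx1 (2.84), the tenascin gene Tnc (2.80), Ahnak2 (2.70), Fbln2 (2.46) and Mdm2 (2.34). In M833 they were Anxa3 (2.66), the chromatin gene Hmga2 (2.58), Tnc (2.56), Gsto1 (2.47) and Ahnak2 (2.43). The 6 lowest ratios of each cell type were those of red cell and liver genes, except for the muscle gene Mylpf in WT. The beta globin gene Hbb-b1 was at -6.90 ± 0.14 in WT and -7.05 ± 0.21 in M833, and the albumin gene Alb at -6.33 ± 0.18 and -6.33 ± 0.16. The other lowest genes of WT were Serpina1e (-6.40), Alas2 (-5.55), Mylpf (-5.53) and the transthyretin gene Ttr (-5.47), and those of M833 were Serpina1e (-6.15), Alas2 (-5.54), Ttr (-5.36) and Apoa1 (-5.02). In WT 1016 features differed at least 2-fold from the reference at an adjusted p under 0.05 in limma, 288 higher and 728 lower. In M833 894 did, 185 higher and 709 lower. The reference carried no spread of its own in these tests, and both sets of ratios share it.

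**Figure D3:**
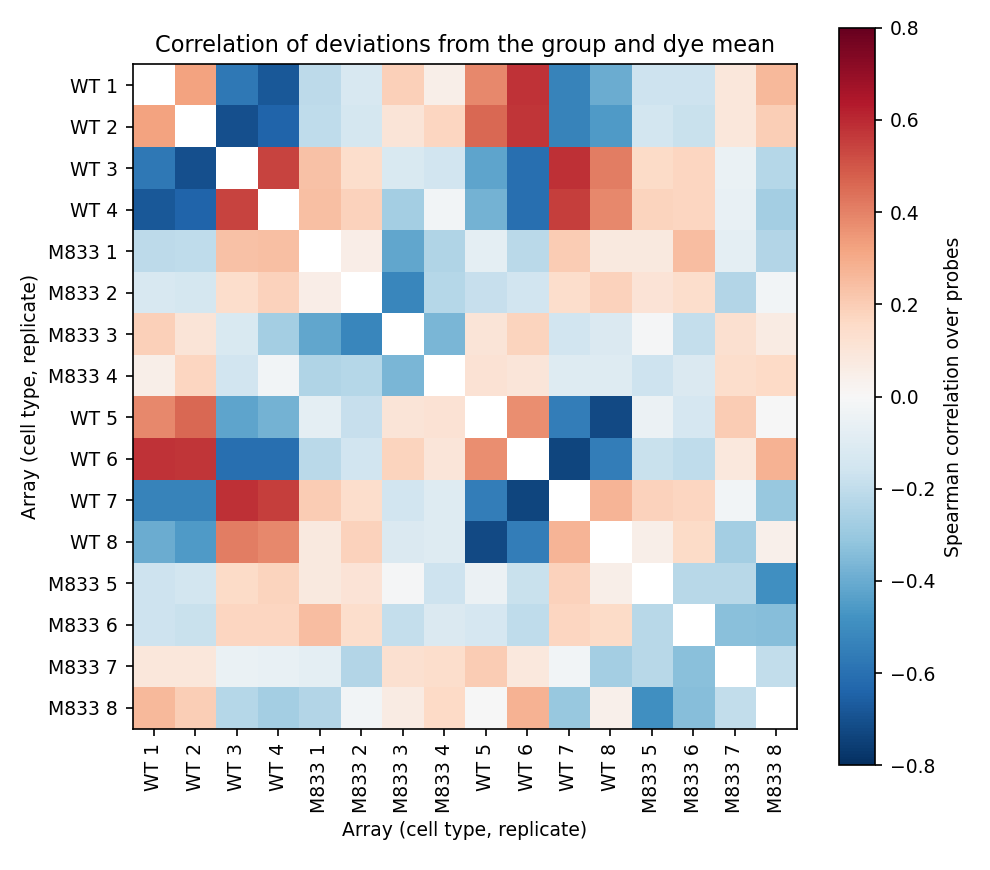
Spearman correlation over probes is shown for each pair of the 16 arrays, computed on deviations from the mean of the cell type and dye orientation. WT replicates 1, 2, 5 and 6 deviated together across dye orientations, as did replicates 3, 4, 7 and 8, with correlations from 0.385 to 0.583, against -0.603 to -0.381 between these sets and 0.0634 to 0.244 within the corresponding sets of M833.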

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

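Of the tests in this part, the count of macrophage genes whose arrays lay apart, both tests on the cell cycle genes and the tests on the sets of WT arrays were chosen after the result was seen, and the second list of leukocyte genes and the splits of the arrays were set before. WT replicate 2 stood apart from the other WT arrays in 4 measures, in each of which the gap to its nearest neighbour, as a share of the whole range of the 8 arrays, exceeded the 95% limit of Dixon's test. Its SD over probes was 1.09 against a median of 0.708 in the others, with a gap of 0.713. It held 49 values above 8 on the log2 scale, from 8.08 to 15.35, and the other arrays 0, with a gap of 1, while the same probes reached at most 2.36 elsewhere. Its mean over the collagen and matrix list was 0.49 against a median of 0.09, with a gap of 0.584, and its mean over the Wnt and BMP list, in which Rspo3 stood at 4.52, was 1.09 against 0.22, with a gap of 0.834. Among the M833 arrays replicate 8 was low over the endothelial markers (-1.61 against -1.29, gap 0.563) and the epithelial markers (-2.41 against -1.99, gap 0.587), and replicate 6 was high over the Wnt and BMP list (0.46 against 0.10, gap 0.543). With 121 groups tested about 6.05 such results arise by chance, where 7 were found. Genes with such a value included Vcan, whose log2 difference was -1.63 with the value and -0.16 without it, neither of them called, and Mad2l1, a spindle checkpoint gene, at -1.38 and not called with it and at -0.38 (adjusted p = 0.0282, limma) without it. These genes were chosen after their values were seen.

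Other splits of the arrays were drawn for each count, 100 in all with the real one, and treated the 16 arrays as independent. For features differing between M833 and WT 1 of the 100 gave as many as the real 3301, and the highest other gave 392, so that chance is excluded only if the arrays are independent. For the 2-fold count 1 of the 100 gave as many as the real 10, with 3 as the highest other, under the same condition. With the mean of each set of 4 arrays that deviated together as 1 replicate both counts were 0, and 2 sets against 2 allow too few splits for a share under 0.05. For lists 7 of the 100 gave as many as the real 9, with 10 as the highest other, so that chance cannot be excluded for the number of lists called. Most of the other splits called at least 1 list, and one with 4 M833 arrays on each side called 10. An adjusted p under 0.05 for a single list in camera at the preset correlation was thus common without the real grouping. For the dye orientation by cell type interaction the real count was 0, which 100 of 100 splits must reach, so that this comparison says nothing about chance. The highest other was 760, and a split with that many points to a structure of the samples, which was not tested on these splits.

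All 7 macrophage and leukocyte markers fell in M833. That only one part of the WT arrays carried this difference is argued against by 6 of the 7 genes, in which every M833 array lay below every WT array in both dye orientations. Fewer macrophages in the M833 cultures is a candidate explanation, and a second list of 58 leukocyte genes, 12 of them measured and none in the first list, had a median log2 difference of -0.21, with 7 lower and none higher, below that of all but 0.02% of 10000 random lists. Such random lists take no account of correlation between the listed genes. Cybb (-0.61) and Ptpn6 (-0.49) fell, as did Cyba (-0.22), which is also expressed widely outside leukocytes, but Fcgr3 (-0.20) did not pass the test, and Lyz2, abundant in macrophages, stood at -0.32 in WT and -1.98 in M833 against the reference. A lower expression of these genes in the cells themselves, with the M833 change, stays open and was not tested.

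Of 31 measured cell cycle genes 24 rose in M833 and 7 did not pass the test. The list lost its call in camera with an estimated correlation (adjusted p = 0.128). Macrophage RNA in WT that dilutes fibroblast RNA would raise fibroblast markers in M833 alike. The cell cycle median lay above the fibroblast median by 0.72 ± 0.13 (bootstrap SE). This gap cannot decide on dilution, since the fibroblast markers were already known to fall, and a fall of their own would hide a dilution. A difference that rests on one set of WT arrays alone is argued against by the list median, which was 0.29 in the lower case when either set was left out. How far culture density or growth state set the size is open, as the labels name neither, and a difference that belongs to the cell type was not tested against them.

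WT arrays fell into 2 sets of 4, and in these Sfn, an epithelial 14-3-3 gene chosen after its values were seen, ranged from -3.45 to -3.19 on replicates 1, 2, 5 and 6 and from -0.87 to -0.77 on the others. M833 arrays split more weakly, with a mean correlation across dye orientations of 0.132 within the corresponding sets and -0.131 between them. Sfn ranged from -1.33 to -1.30 on M833 replicates 1, 2, 5 and 6 and from -1.97 to -1.83 on the other M833 arrays. A steady trend along the slide number series is argued against by the 2 WT arrays with the lowest and the 2 with the highest numbers, which deviated together with correlations from 0.387 to 0.583 and a mean of 0.483. Position in that series in another form stays open, since the sets made 3 runs along it, as few as in 11.4% of all orders, although the one pair of neighbouring slides from different sets correlated at -0.734. The sets were found on deviations from the mean of each dye orientation, which removed a dye effect equal on all arrays, and a dye bias of different strength stays open, since the set difference followed the dye effect over features with rho = 0.266 in the Cy5 arrays and 0.040 in the Cy3 arrays. Whether 2 RNA sources lie behind the sets cannot be told apart from other causes, since the mean correlation of 0.491 within sets comes from the pairs that defined them, and no biological explanation was tested.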

How the results depend on the processing

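The settings with sets of WT arrays left out, as a random block or as 1 replicate, and with extreme values missing, were chosen after the data were seen. For features differing between M833 and WT the count of 3301 became 2000 with no dye term, 835 with Cy5 arrays alone, 1100 with Cy3 arrays alone, 1465 with the sets as a random block, all of them among the 3301, and 0 with the mean of each set as 1 replicate. It became 2206 without the second slide number series and 3887 with array weights. Without WT replicates 1, 2, 5 and 6 it was 4328, and without WT replicates 3, 4, 7 and 8 it was 4629. Fewer arrays enter the single-dye fits. As dye orientation was balanced in each cell type, dropping its term left the differences as they were and put the dye bias into the spread. The cause of the other changes was not tested. The 2-fold count of 10 became 58 with scaling between arrays (2 higher and 56 lower), 38 without WT replicates 1, 2, 5 and 6, 55 without WT replicates 3, 4, 7 and 8, and 0 with set means. The 9 lists became 1 with the estimated correlation, 18 with fry, 6 with scaling between arrays, 7 without WT replicates 1, 2, 5 and 6 and 4 without WT replicates 3, 4, 7 and 8, and numbered 8 to 11 in the other settings. In these the fibroblast markers lost their call with no dye term (adjusted p = 0.104) and in Cy5 arrays alone (adjusted p = 0.0509), the Hox list with array weights (adjusted p = 0.0533) and in Cy3 arrays alone (adjusted p = 0.0556), and skeletal muscle in Cy3 arrays alone (adjusted p = 0.0614). The interaction count of 0 became 7 without the second slide number series. Under scaling Esrp1 (-0.035), Sdha (-0.014), Dlk1 (-0.22) and Me1 (0.037) changed sign. The median absolute deviation over probes, scaled to an SD, ran from 0.341 to 0.487 over the WT arrays and from 0.296 to 0.408 over the M833 arrays. Scaling evens this spread, so that WT ratios shrink relative to those of M833. How far this accounts for the calls and signs that changed under scaling was not tested. Leaving out each array in turn gave 2878 to 3295 features, 9 to 13 at 2-fold, 8 to 10 lists, 0 to 0 interactions, and 1009 to 1038 features against the reference in WT and 876 to 899 in M833. In the settings other than single arrays left out, 1214 values of named genes kept direction and call, 475 lost the call, 1 gained it and 4 changed sign. Both filters on missing values were void because no value was missing. Turning all signs, which would exchange higher and lower in every count and rank and leave sizes and p-values as they are, was not run because the direction was taken as likely, and camera with the sets as a block was not run. No paired analysis was possible because the labels carry no replicate numbers shared by the cell types. Without intensities the signal over background, and with it any limit on dim probes, is unknown.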

Other observations

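The lysosomal list was drawn up after several cathepsin genes had been seen to fall, and its test was set before its members' values were seen, while the left-out sets of arrays and of cathepsin genes were chosen after. Lysosomal genes were lower in M833. Of 36 measured genes of a list of 58, which left out the cathepsin genes first seen and kept Ctsc (-0.60), Ctsh (-0.44) and Ctsa (-0.33), 24 fell, 1 rose and 11 did not pass the test. Lgmn, encoding an asparaginyl endopeptidase, fell by 0.60 ± 0.06, the saposin precursor gene Psap by 0.45 ± 0.03, Gm2a by 0.52 ± 0.05 and the membrane protein gene Lamp1 by 0.24 ± 0.04 (log2, SE, n = 8 per cell type), while Gga2 rose by 0.21 ± 0.06. In 18 of the 36 every M833 array lay below every WT array in both dye orientations.

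A hypothesis was that lysosomal genes fell as a group in M833, beyond the cathepsins first seen. The median log2 difference of the list was -0.24, below that of each of 10000 random lists matched on mean ratio, whose median was -0.05. Random lists take no account of correlation between the genes of a list, so this rank is not a p-value for the group. Without the 3 cathepsin genes left in the list it was -0.24, with 21 genes lower and 1 higher. It was -0.33 without WT replicates 1, 2, 5 and 6 and -0.17 without WT replicates 3, 4, 7 and 8, with 29 and 20 genes lower. Macrophages are rich in many of these transcripts, so the decrease may share a source with that of the leukocyte markers, which was not tested.

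Several genes differed far more between WT arrays than between cell types, chosen after their values were seen. Parm1 lay between -1.94 and -1.75 on WT replicates 1, 2, 5 and 6, between 0.37 and 0.52 on the other WT arrays, and between -0.73 and -0.43 on the M833 arrays. Col6a1 lay between -0.20 and -0.02, between -2.16 and -1.96, and between -1.71 and -1.20 on the same sets. The median SD within cell type and dye orientation was 0.121 in WT and 0.0807 in M833 over all features, and in the cholesterol and fatty acid synthesis list 0.292 in WT and 0.0969 in M833.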
